A study of Rattus norvegicus with 16 samples.

How the data were processed

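Liver RNA of female Sprague-Dawley rats on 4 diets was hybridised to Affymetrix whole-transcript exon arrays, 1 biotin-labelled sample per array and 4 arrays per diet. The deposited values were 1 intensity per probe set and array, on a linear scale, for 887828 probe sets on 16 arrays with no missing value and 0 columns of other samples. All intensities made by the authors were above 0 and the array medians lay between 22.2 and 23.8. The summary of probes, the background correction and the normalization are not given in the sources used here. The genome build rn4 stands in the submitters' processing notes, and no coordinates are given here, since the gene table used for names belongs to another assembly, GRCr8. Background correction could not be varied, because only the processed intensities were used, and scan dates were not used here.

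Arrays were assigned to groups from their titles, which also number the replicates from 1 to 4. The platform annotation paired 177688 probe sets (20.0%) with exactly 1 gene symbol and 2920 with several, and 707220 had no gene name here. Of its 14903 symbols 11393 were current in the RefSeq table, 3454 were updated through a synonym and 56 were kept as given, which left 14839 genes, 54 of them joined from more than 1 older symbol. Only probe sets paired with 1 symbol entered the gene values.

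Intensities were transformed as log2(intensity + 1), which shrinks the changes of dim genes. A probe set was kept if its mean over the 16 arrays reached the 75th percentile of all probe sets (log2 value 6.01, intensity 63.6), which kept 103692 named probe sets of 12156 genes, with a median of 6 per gene. Each gene was summarised by median polish over its kept probe sets. A group whose mean gene value lay under that threshold is called dim here; its level is not shown to be above background, and the size of a change from or to it is uncertain. Probe sets of genes with close relatives (Ugt1a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Acot1 and Acot2) can read more than 1 gene, and their values are uncertain in that respect. Array values have no count behind them, so the number of arrays limits the precision; the median standard error of a log2 difference was 0.166.

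A linear model with a mean per group was fitted to all 16 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with version 1.17.8 of data.table, and 6 contrasts were tested, each diet against Control and each pair of compounds. The p-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05, and rose, fell, passed and called refer to this threshold. All adjusted p-values of genes in the text come from this limma model. Genes were also counted at a change of 1.5-fold or more. The test was run on simulated data: with known changes planted in a simulated comparison of UAB30 against Control over 12156 genes, 23.9% of 1.5-fold, 73.1% of 2-fold and 100% of 4-fold changes were recovered, 1.50% of calls were unchanged genes, and 1 comparison with no change gave 0 calls. That run is no error rate, since 100 simulated pairs of unchanged groups with the same controls gave up to 369 shared calls. Those pairs were drawn with replacement from the deviations of the 16 arrays within groups, so a simulated group can hold 1 array more than once, which narrows its spread.

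The design, the alternatives, the rule for named genes and 35 gene lists (23 of pathways and 12 of cell type markers) were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with adjustment over the 210 tests of 35 lists in 6 contrasts, and again with a correlation estimated from the data and with fry. Only the fatty acid synthesis list, in Targretin against Control and against UAB30, held its camera call with an estimated correlation. Not every called list is described. Each count of list members was also made with p-values adjusted over the list alone. Named genes were the 8 largest increases and 8 largest decreases against Control, or the 5 largest of each between compounds, among called genes whose 4 arrays of a group all lay on 1 side of the 4 of the other. To these were added, for each list with 3 or more called members, the pair with the smallest adjusted p, and 26 fixed genes. Of the fixed genes 21 were tested, and the others are not reported here. Genes outside the rule were named after their values were seen: Cyp2c22 and Cyp1b1 with UAB30, Lrat, Msmo1, Npc2, Fads2, Gstp1 and Gclc with MeUAB30, Fads1, Fads2, Insig1, Fdft1, Crot and Nr1i3 with Targretin, Crot and Decr2 between the analogs, and the genes of opposite change in 2 diets.

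Because the 3 diets share the Control arrays, correlations and overlaps were set beside 100 simulated pairs of unchanged groups, beside the overlap of independent lists, and beside values with the 4 Control arrays split 2 and 2. The Targretin score of an array was the mean of its log2 values, signed by the Targretin change, over genes called in a fit of the 8 Targretin and Control arrays, and MeUAB30 was compared with UAB30 by a two-sided exact permutation test over 70 permutations. Alternatives covered the filter, the pseudocount (16), genes with 3 or more kept probe sets, the gene summary, normalization, array weights, the variance model, the arrays in the fit, the replicate number as a block, and each array left out in turn. Leaving out the arrays that stood apart and adding the intensity range as a covariate were chosen after seeing the data.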

Results

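Liver RNA from female Sprague-Dawley rats, 5 weeks of age, on 1 of 4 diets was measured on whole-transcript exon arrays. The diets with a compound were fed for 7 days, and the labels used here state no period for Control. The diets held UAB30 (200 ppm), 4-methyl-UAB30 (here MeUAB30, 200 ppm), Targretin (150 ppm) or no added compound (Control), and each group had 4 arrays, 16 in all. The 3 compounds are agonists of the retinoid X receptor (RXR), a nuclear receptor that binds DNA as the partner of other nuclear receptors, among them the retinoic acid, peroxisome proliferator-activated, liver X and xenobiotic receptors; Targretin is bexarotene. The comparisons addressed which liver genes each agonist changed and how far the agonists differed. The Targretin dose was lower than that of both other compounds, so comparisons with Targretin are not at matched doses, whereas UAB30 and MeUAB30 were fed at the same level. Each diet was given to 1 group, so a batch of diet cannot be told apart from its compound. The labels do not state that each array came from a separate animal, so p-values measure the spread between these arrays, which may in part be technical.

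Median intensities of the 16 arrays lay between 22.2 and 23.8, and 12156 genes were bright enough to be tested. Correlations between arrays ranged from 0.893 to 0.983, and no array was a copy of another. UAB30 array 3, MeUAB30 array 1, Targretin array 2 and Control array 3 had the lowest mean correlation with their group mates, down to 0.925 for Control 3 and 0.929 for Targretin 2. These arrays lay at the high end of the first principal component, which held 31.7% of the variance of the gene values. Each had the narrowest intensity range of its group, the log2 ratio of the 99th percentile to the median, with 6.06 on Control 3, 6.08 on Targretin 2, 6.14 on UAB30 3 and 6.15 on MeUAB30 1. The range of UAB30 2, which did not stand apart, was also 6.15, and the widest was 6.28 on MeUAB30 4.

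**Figure D1:**
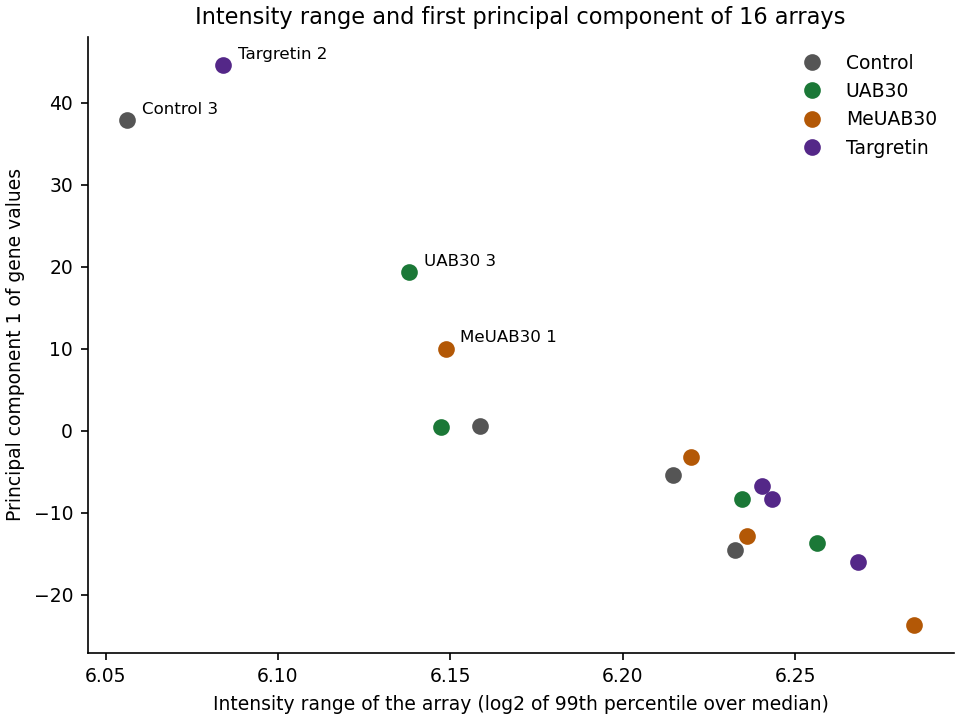
Intensity range of each array (x axis, log2 of the 99th percentile over the median) against its score on principal component 1 of the gene values (y axis), 1 point per array, coloured by diet. Control 3 and Targretin 2, with ranges of 6.06 and 6.08, had the highest component scores, 37.9 and 44.6.

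With UAB30, the gene that changed most was Cyp1a1, a cytochrome P450 that is the standard target of the aryl hydrocarbon receptor (AhR). It rose 53.6-fold, from 6.10 ± 0.42 in Control to 11.85 ± 0.28 in UAB30 livers (log2 intensity, mean ± SD, n = 4; log2 change 5.74, SE 0.37, adjusted p = 1.59e-07). The Control level lay close to the filter threshold of 6.01, so the fold is uncertain. Its neighbour in function Cyp1a2 rose 1.99-fold from an already high level (adjusted p = 0.000585), and Nqo1, a quinone reductase, rose 2.52-fold (adjusted p = 0.00962). Of the 19 measured members of the AhR and Nrf2 response list these 3 rose and none fell, against 4 that rose when adjusted over the list alone (median log2 change 0.19). The list moved up against all other genes (camera adjusted p = 8.35e-07), but not with a correlation estimated from the data (adjusted p = 0.3 with an estimated correlation). Cyp1b1, measured by 1 probe set, had a log2 change of 1.54 and an adjusted p of 0.0522.

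Altogether 10 of the 12156 genes passed the threshold with UAB30, 9 higher and 1 lower, each by at least 1.5-fold, against 948 at an unadjusted p under 0.05. Besides those named, the higher genes were Zbtb16, a zinc finger transcription factor (3.4-fold, adjusted p = 0.017), Egr1, an immediate early transcription factor (2.81-fold, adjusted p = 0.000212), the clock repressor Bhlhe40 (2.09-fold, adjusted p = 0.0239), Crot, the peroxisomal carnitine octanoyltransferase (2.06-fold, adjusted p = 0.0239), and the glucuronosyltransferase Ugt1a6 (1.98-fold, adjusted p = 0.0392). Ugt1a6 was read by 2 probe sets and shares exons with the other Ugt1a genes, so its value is uncertain. The last higher gene, Cyp2c22, named after its values were seen, rose by 0.98 on the log2 scale (adjusted p = 0.000625). Entpd7, a nucleoside triphosphate diphosphohydrolase, was the gene that fell, to a level 1.83-fold lower (adjusted p = 0.00962). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood 4.12-fold lower with all 4 UAB30 arrays below all 4 Control arrays, but missed the threshold (log2 change -2.04, SE 0.39, adjusted p = 0.0522).

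Lipid oxidation lists moved up with UAB30 in camera at the preset correlation, although few single members passed. Of 20 peroxisomal fatty acid oxidation genes 19 had a positive log2 change, and Crot alone rose over all genes, against 4 when adjusted over the list alone (median 0.20, camera adjusted p = 5.52e-06, adjusted p = 0.7 with an estimated correlation). The mitochondrial fatty acid oxidation and ketogenesis list had a median of 0.23 over 23 genes, 20 of them positive, with 0 that rose over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.000163, 0.7 with an estimated correlation). Among 22 CAR and PXR xenobiotic metabolism genes, targets of the constitutive androstane and pregnane X receptors, Ugt1a6 rose, and 7 rose when adjusted over the list alone (median 0.26, camera adjusted p = 0.000143, 0.7 with an estimated correlation). With fry the peroxisomal, mitochondrial and CAR and PXR calls were lost too (fry adjusted p = 0.126, 0.144 and 0.144). None of the 18 retinoic acid response and retinoid handling genes passed; Cyp26a1, the retinoic acid hydroxylase, had a log2 change of 0.64 (SE 0.24, adjusted p = 0.509). None of the 20 SREBP-1c and LXR fatty acid synthesis genes passed either, against 3 when adjusted over the list alone, and their camera adjusted p of 0.0242 became 0.908 with an estimated correlation and 0.186 without the 4 arrays that stood apart, and the call was also lost without UAB30 1 or Control 2 or 3 (up to 0.217) and with the intensity range as a covariate (0.0726). Kupffer cell and macrophage markers had a median log2 change of 0.42 over 14 genes (camera adjusted p = 0.0147, 0.961 with an estimated correlation, 0.092 without the 4 arrays, up to 0.387 without UAB30 1 or Control 3, 0.101 with the intensity range as a covariate, 0 members passing).

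Cyp1a1, Cyp1a2 and Egr1 passed whichever array of these groups was left out, whereas 6 other calls were lost without some arrays. Nqo1 lost its call without UAB30 1, Control 1 or Control 4 (adjusted p up to 0.0602) and Entpd7 without UAB30 4, Control 1 or Control 4 (up to 0.0598). Zbtb16 lost it without UAB30 1 or 3 or Control 1, 3 or 4 (up to 0.0907), Bhlhe40 without any UAB30 array or Control 3 or 4 (up to 0.0959), Crot without UAB30 1, 2 or 4 or Control 1, 3 or 4 (up to 0.123), and Ugt1a6 without any array but Control 2 (up to 0.148). The count of 10 became 36 without Control 2, 6 without Control 3 or UAB30 4, 5 without UAB30 1 or Control 1 and 4 without Control 4, and it was 31 without the 4 arrays that stood apart. The share of higher genes, 90.0%, was 51.6% without those 4 arrays, 35% of 40 without Targretin 2 and Control 3 and 50.9% of 106 with the intensity range as a covariate, all chosen after seeing the data. It was 65.9% of 44 with array weights, 77.8% of 9 without UAB30 2 and 78.6% with quantile normalization.

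**Figure D2:**
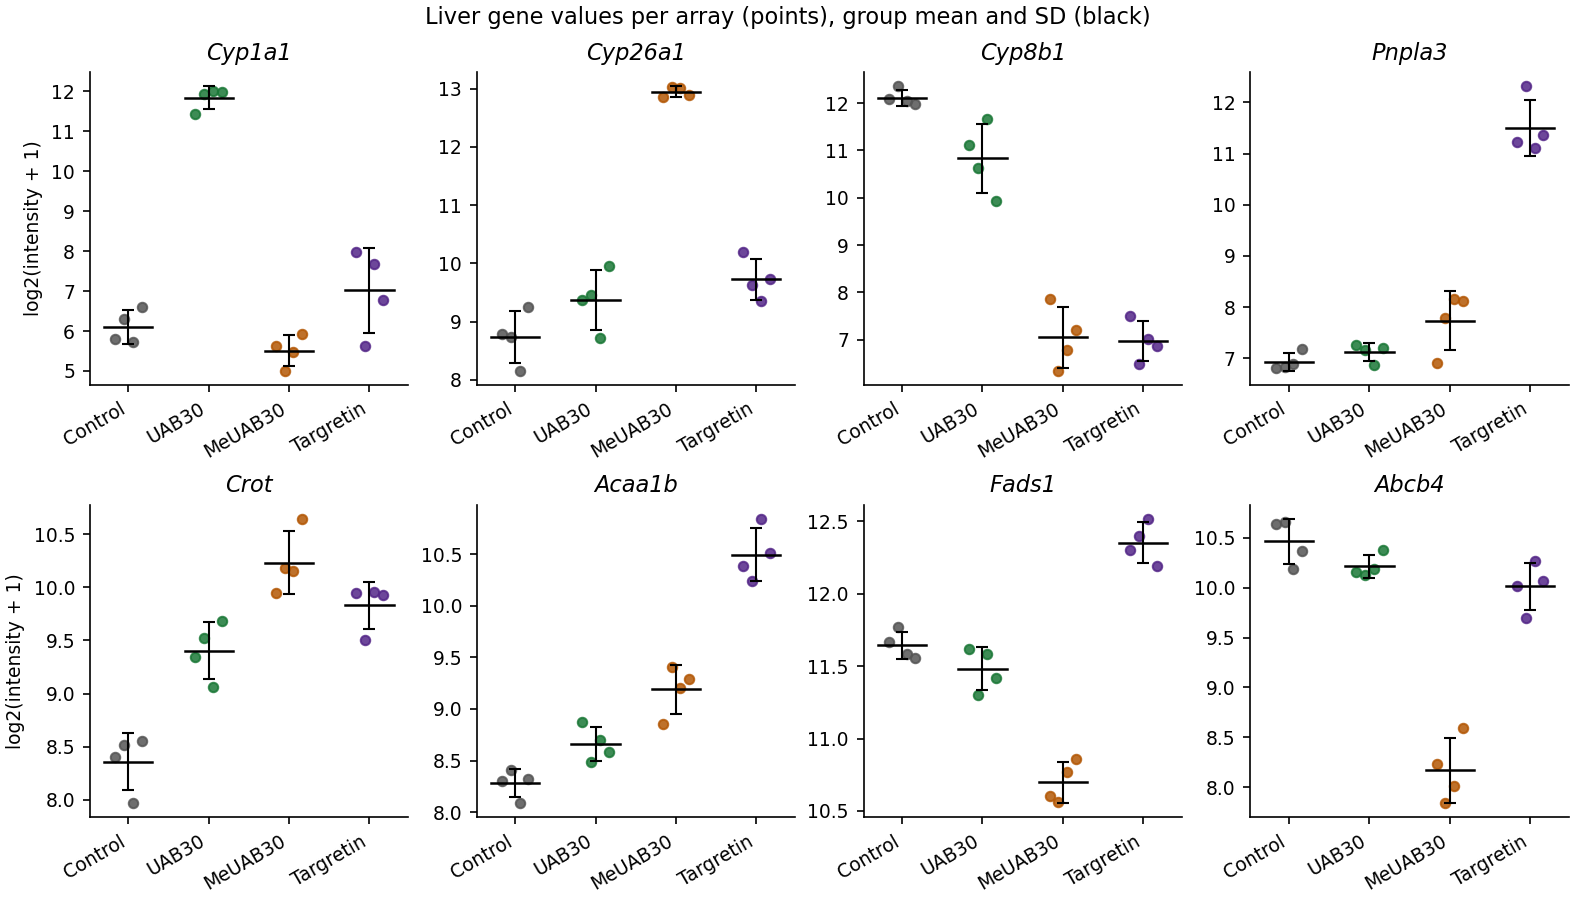
Values of 8 genes on each array (y axis, log2 of intensity + 1; points, 4 per diet on the x axis) with the group mean (black bar) and SD (error bar). Cyp1a1 averaged 11.85 with UAB30 and 6.10 in Control, Cyp26a1 12.95 with MeUAB30 and 8.73 in Control, and Pnpla3 11.50 with Targretin and 6.93 in Control.

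MeUAB30 had more called genes, and the largest increase among them was in Cyp26a1, the retinoic acid hydroxylase. Cyp26a1 rose 18.6-fold, from 8.73 ± 0.45 to 12.95 ± 0.09 (log2 intensity, mean ± SD, n = 4; log2 change 4.22, SE 0.24, adjusted p = 2.25e-08), and Cyp26b1, which encodes a second retinoic acid hydroxylase, rose 6.13-fold (SE 0.28 on the log2 scale, adjusted p = 2.16e-05). The Control arrays of Cyp26b1 lay between 6.12 and 6.49, close to the filter threshold, so its fold is uncertain. Lrat, which esterifies retinol for storage, rose by 0.83 on the log2 scale (adjusted p = 0.00754). These 3 of 18 retinoid list members rose and none fell, against 4 that rose when adjusted over the list alone (median 0.26, camera adjusted p = 0.00841, 0.7 with an estimated correlation). Rarb, the retinoic acid receptor beta, had a log2 change of 0.30 and did not pass (SE 0.14, adjusted p = 0.218).

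Bile acid genes changed in both directions with MeUAB30. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the proportion of cholic acid, fell by 5.06 on the log2 scale (SE 0.33, 33.4-fold lower, adjusted p = 7.89e-08, 2 probe sets). Abcb4, the canalicular phospholipid transporter, fell by 2.29 (adjusted p = 2.29e-07), and Cyp7a1 fell by 1.76 with a wide spread between the MeUAB30 arrays (9.36 ± 1.11, adjusted p = 0.00795). Nr0b2, the small heterodimer partner that represses bile acid synthesis genes, rose 2.63-fold (adjusted p = 0.0001). Of 22 bile acid synthesis and transport genes 3 rose and 5 fell, and 5 rose and 6 fell when adjusted over the list alone (median -0.20, camera adjusted p = 0.0135, 0.81 with an estimated correlation, 0.0631 without the 4 arrays that stood apart, 0.055 with the intensity range as a covariate and 0.0573 without Control 2). The sterol half-transporters Abcg5 and Abcg8 fell to dim levels, by 2.31 and 1.69, sizes that are uncertain, the fallen pair among 14 LXR cholesterol efflux and transport genes, of which Npc2 rose; 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.221). Among 20 cholesterol synthesis genes Cyp51, Msmo1 and Idi1 fell and none rose (Idi1 lost its call without MeUAB30 1, 2 or 3 or Control 1, 2 or 4, adjusted p up to 0.13), against 1 rising and 5 falling when adjusted over the list alone (median -0.14, camera adjusted p = 0.00788, 0.955 with an estimated correlation, 0.0677 without the 4 arrays and up to 0.129 without MeUAB30 1 or Control 2).

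Some fatty acid oxidation and synthesis genes rose with MeUAB30, and others of the mitochondrial and synthesis lists fell. Of 20 peroxisomal genes 10 rose and none fell, 13 and 1 when adjusted over the list alone (median 0.49, camera adjusted p = 7.39e-05, 0.74 with an estimated correlation). Crot rose 3.66-fold (adjusted p = 5.25e-06), Decr2, the peroxisomal dienoyl-CoA reductase, rose 3.16-fold (adjusted p = 5.25e-06), and Ehhadh rose 1.36-fold (adjusted p = 0.0189; lost without MeUAB30 3 or 4, up to 0.0675). In the mitochondrial list 6 of 23 rose, among them Acsm3, dim in Control, and Hadh (1.54-fold), and 1 fell; 8 rose and 2 fell when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0938). Of 20 SREBP-1c and LXR fatty acid synthesis genes 9 rose and 2 fell, 12 and 2 when adjusted over the list alone (median 0.53, camera adjusted p = 0.0026, 0.724 with an estimated correlation). Thrsp, a nuclear regulator of lipogenesis, rose 3.16-fold (adjusted p = 1.47e-06) and Scd, the stearoyl-CoA desaturase, 1.83-fold (adjusted p = 0.000917). Fads1 and Fads2, the desaturases of polyunsaturated fatty acids, fell by 0.95 and 0.67 (adjusted p = 0.0001 and 0.00132). Of 24 lipid droplet and fatty acid uptake genes 4 rose, the lipid droplet protein Cidec 2.05-fold among them, and none fell, also when adjusted over the list alone (camera adjusted p = 0.238).

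Xenobiotic genes did not move one way with MeUAB30. Of 22 CAR and PXR genes 5 rose and 5 fell, 6 and 5 when adjusted over the list alone (camera adjusted p = 0.795): Por, the electron donor of microsomal P450 enzymes, rose 1.95-fold (adjusted p = 0.00153) and Cyp2a1 fell by 1.11 (adjusted p = 4.46e-05). In the AhR and Nrf2 list Nqo1 rose 2.97-fold and Gstp1 rose, while Cyp1a2 fell by 0.88 (adjusted p = 0.00017) and Gclc fell. That list had 2 rising and 3 falling of 19 when adjusted over the list alone (camera adjusted p = 0.507). Outside the lipid and retinoid lists large increases were those of Acmsd, a decarboxylase of the tryptophan to NAD pathway (7.36-fold, adjusted p = 1.08e-07), the sulfotransferase Sult1c3 (6.98-fold), the metallothionein Mt2A (5.87-fold), Rgs16, a regulator of G protein signalling (5.53-fold), and Gnmt, glycine N-methyltransferase (4.79-fold). Spink1, a trypsin inhibitor, also rose, from a dim level of 4.75 ± 0.63 to 7.74 ± 0.51, so its fold is uncertain. Ddc, the aromatic amino acid decarboxylase, and Hyal1, a hyaluronidase, fell by 2.19 and 1.91, and Plppr1 fell to a dim level (adjusted p = 3.44e-06). Among urea cycle and amino acid breakdown genes 5 of 31 rose, with Gls2 at 2.08-fold, and 6 fell, with Cps1, the entry enzyme of the urea cycle, lower by 1.49-fold; 6 and 6 did so when adjusted over the list alone. Pericentral hepatocyte markers, Cyp7a1, Cyp8b1 and Cyp1a2 among them, had 1 member that rose and 6 that fell of 15, 3 and 6 when adjusted over the list alone (median -0.01, camera adjusted p = 0.00796, 0.81 with an estimated correlation and 0.0968 without Control 2), and periportal markers 3 that rose and 2 that fell of 14, 4 and 2 when adjusted over the list alone (camera adjusted p = 0.756).

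In total 1209 genes passed with MeUAB30, 963 higher and 246 lower, and 885 of them changed by at least 1.5-fold. The share of higher genes, 79.7%, was 61.3% of 2452 genes without the 4 arrays that stood apart, 64.3% of 2775 with array weights 47.2% of 3013 with the intensity range as a covariate and 54.5% of 2349 without Targretin 2 and Control 3, all but the array weights chosen after seeing the data. It was 62.8% of 1268 without Control 3. The count fell to 638 without Control 4, 689 without MeUAB30 3, 752 without MeUAB30 2 and 792 without MeUAB30 4.

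**Figure D3:**
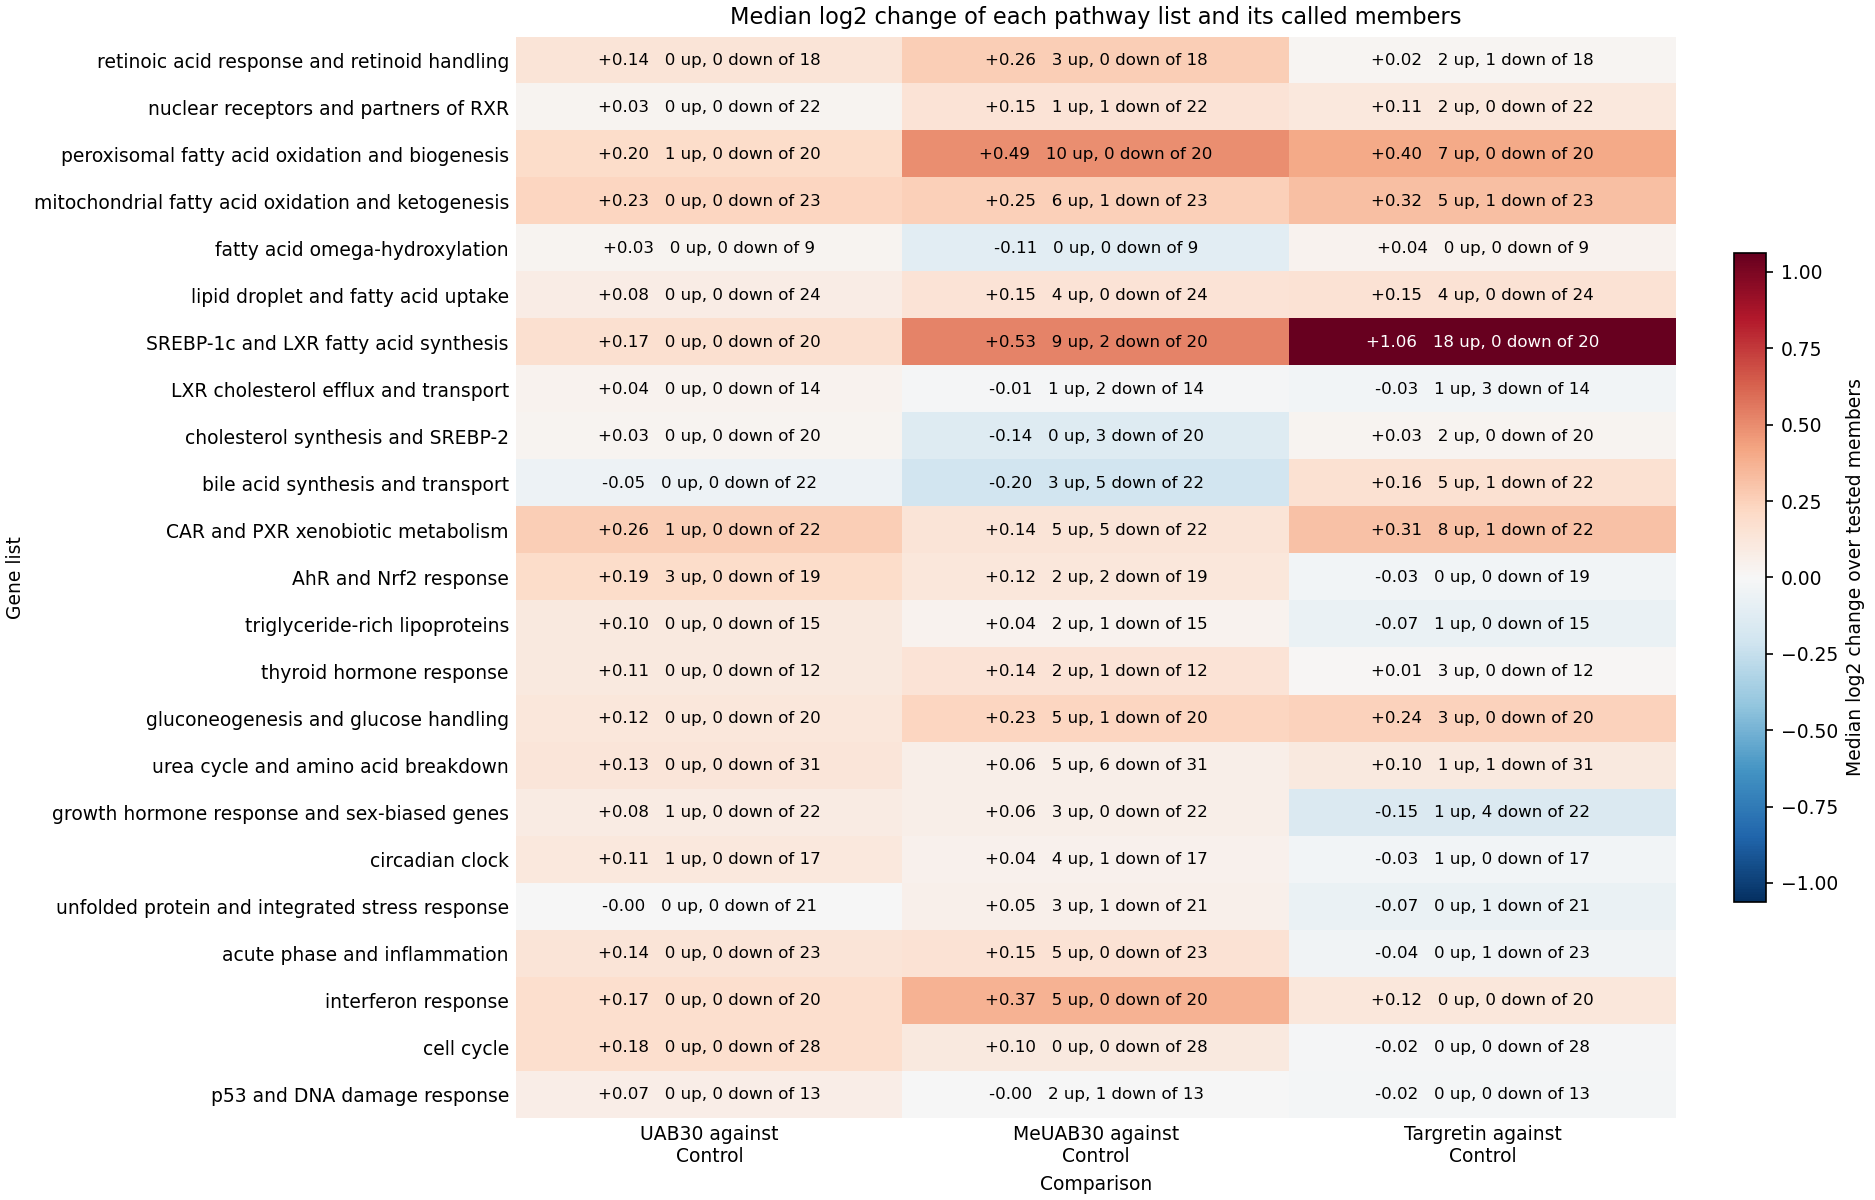
Median log2 change of the tested members of 23 pathway lists (y axis) in each diet group against Control (x axis), with the numbers of members that rose and fell at an adjusted p under 0.05; red is higher and blue lower. The SREBP-1c and LXR fatty acid synthesis list had a median of 0.17 with UAB30, 0.53 with MeUAB30 and 1.06 with Targretin.

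Targretin raised the genes of fatty acid synthesis more widely than any other list. Of 20 SREBP-1c and LXR fatty acid synthesis genes 18 rose and none fell, 19 when adjusted over the list alone (median 1.06, camera adjusted p = 4.39e-46), and this call held with an estimated correlation (adjusted p = 0.00532). Pnpla3, a lipase of lipid droplets, rose 23.7-fold, from 6.93 ± 0.17 to 11.50 ± 0.55 (log2 intensity, mean ± SD, n = 4; log2 change 4.57, SE 0.26, adjusted p = 1.99e-08). The fatty acid elongase Elovl6 rose 5.96-fold (adjusted p = 0.000144), malic enzyme Me1 5.09-fold (adjusted p = 1.80e-06), Scd 2.87-fold, Thrsp 2.59-fold and Srebf1, the gene of the SREBP-1 transcription factor itself, 2.41-fold (SE 0.23 on the log2 scale, adjusted p = 0.0047). Fads1 and Fads2 rose by 0.71 and 0.88 on the log2 scale. Abca1 and Abcg1, sterol transporters that are targets of the liver X receptors, did not pass (log2 changes -0.13 and -0.27, adjusted p = 0.887 and 0.658), and Abcg5 and Abcg8, the second of them dim with Targretin, fell by 1.62 and 1.76 (adjusted p = 0.0175 and 0.0033; the Abcg5 call was lost without Control 1 or Control 2, up to 0.0594). In that LXR cholesterol efflux list Lpcat3 rose 1.74-fold, and 1 of 14 genes rose and 3 fell, 2 and 3 when adjusted over the list alone (camera adjusted p = 0.424). Insig1 and Fdft1 were the members of the cholesterol synthesis list that rose, of 20, with 5 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.131).

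Some fatty acid oxidation genes rose with Targretin, and Cpt1a fell. Of 20 peroxisomal genes 7 rose and none fell, 13 when adjusted over the list alone (median 0.40, camera adjusted p = 2.13e-18, 0.339 with an estimated correlation). The thiolase Acaa1b rose 4.64-fold (adjusted p = 9.78e-08), Ehhadh, the bifunctional enzyme, 2.79-fold (adjusted p = 5.53e-07), and Crot by 1.47 on the log2 scale. In the mitochondrial list 5 of 23 rose, 13 when adjusted over the list alone, among them Acsm3, dim in Control, the thioesterase Acot2 at 5.21-fold and Pdk4, an inhibitor of glucose oxidation, at 2.24-fold (list median 0.32, camera adjusted p = 1.17e-09, 0.619 with an estimated correlation). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, was the member that fell, by 0.90, with an adjusted p of 0.0289 that rose to at most 0.114 and lost the call without Targretin 2, Targretin 4, Control 1 or Control 2. Acot1 rose 4.4-fold and Dgat2, which completes triglyceride synthesis, 1.72-fold, among the 4 of 24 lipid droplet and uptake genes that rose, with 6 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0026, 0.7 with an estimated correlation). Acot1 and Acot2 are close in sequence, so their probe sets may read both.

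Bile acid, xenobiotic and retinoid genes were also among the named changes with Targretin. Cyp8b1 fell by 5.14 (35.2-fold lower, SE 0.33, adjusted p = 6.14e-08), while Cyp7a1 had a log2 change of 0.31 that did not pass (SE 0.39, adjusted p = 0.895). Nr0b2 rose 2.39-fold and Abcb11, the bile salt export pump, 1.57-fold (adjusted p = 0.000426 and 0.00551). Of 22 bile acid genes 5 rose and 1 fell, 7 and 3 when adjusted over the list alone (median 0.16, camera adjusted p = 0.0257, 0.908 with an estimated correlation, 0.106 without the 4 arrays, and up to 0.12 without Targretin 2 or 3 or Control 3 or 4). Among 22 CAR and PXR genes 8 rose and 1 fell, 9 and 1 when adjusted over the list alone (median 0.31, camera adjusted p = 6.48e-06, 0.7 with an estimated correlation). Cyp2b2 rose 11.3-fold on 1 probe set, which near-identical Cyp2b genes may share, Cyp3a23-3a1 2.31-fold, and Nr1i3, the gene of the constitutive androstane receptor, by 1.47 on the log2 scale (adjusted p = 0.00411). Akr1b7, an aldo-keto reductase, fell by 1.19. None of the 19 AhR and Nrf2 genes passed (median -0.03). In the retinoid list Aldh1a1, which makes retinoic acid, rose 3.39-fold, Cyp26a1 rose 2-fold (adjusted p = 0.0365) and Lrat fell by 0.75 (adjusted p = 0.0357); the Cyp26a1 call was lost without Targretin 1, Targretin 4, Control 1, Control 2 or Control 3 (adjusted p up to 0.13). The Lrat call was lost without Targretin 2, 3 or 4 or Control 1, 2 or 4 (adjusted p up to 0.126). The list gave 3 rising and 1 falling of 18 when adjusted over the list alone (camera adjusted p = 0.442). Further large decreases were A1bg (7.32-fold lower, adjusted p = 0.0096), whose Targretin arrays spread widely (SD 1.85; log2 change -2.06 without Targretin 2 and -3.55 without Targretin 1), Nrep (4.63-fold), Inhbe, a subunit of activin E (3.76-fold), Slc28a2, a nucleoside transporter (3.29-fold, adjusted p = 2.02e-06), Car12, a carbonic anhydrase (3.19-fold), and Esr1, the estrogen receptor alpha (3.18-fold, 2 probe sets). Rgs16 rose 5.47-fold, and Spink1, dim in Control, rose to 7.57 ± 0.68. Erythroid markers had medians of -0.19, -0.22 and -0.39 for UAB30, MeUAB30 and Targretin over 8 genes (camera adjusted p = 0.0242, 0.0324 and 0.00114; 0.65, 0.7 and 0.3 with an estimated correlation; 0.0729 for MeUAB30 without the 4 arrays), with 0, 2 and 1 members that fell and 0, 2 and 4 when adjusted over the list alone. The UAB30 call of that list was lost without UAB30 1 or 2 or Control 1 or 3 (adjusted p up to 0.0746) and the MeUAB30 call without Control 1 or 3 (up to 0.0598). Both were lost without Targretin 2 and Control 3, with the intensity range as a covariate and with no filter on dim probe sets.

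With Targretin 265 genes passed, 183 higher and 82 lower, 231 of them by at least 1.5-fold. The higher share of 69.1% was 68.0% of 497 genes without the 4 arrays that stood apart but 31.0% of 1275 with the intensity range as a covariate, both chosen after seeing the data. The share was 81.2% of 399 without Targretin 2 and 54.2% of 253 without Control 3. The count was 399 without Targretin 2, 169 without Targretin 4 and 116 in a fit of the 8 arrays alone.

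At the matched dose of 200 ppm, UAB30 and its 4-methyl analog differed in 172 genes, 87 higher and 85 lower with MeUAB30. Cyp1a1, the AhR target, was lower with MeUAB30 than with UAB30 (5.51 ± 0.38 against 11.85 ± 0.28, log2 intensity, mean ± SD, n = 4; limma adjusted p = 3.16e-08). The MeUAB30 level was dim, so the size of that difference is uncertain. Cyp1a2 was 3.66-fold lower (log2 difference -1.87, 95% interval -2.12 to -1.62). Cyp1a2 and Ugt1a6 passed in both groups against Control in opposite directions, higher with UAB30 and lower with MeUAB30. Their difference therefore also passed (Ugt1a6 -1.63, 95% interval -2.00 to -1.25, limma adjusted p = 4.66e-05). Of 19 AhR and Nrf2 genes 4 were lower with MeUAB30 and none higher, 5 when adjusted over the list alone (camera adjusted p = 7.19e-06, 0.366 with an estimated correlation).

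The retinoic acid hydroxylases went the other way: Cyp26a1 was 11.9-fold higher with MeUAB30 (log2 difference 3.58, 95% interval 3.07 to 4.09) and Cyp26b1, dim with UAB30, was higher too (adjusted p = 1.21e-05). In the retinoid list 3 of 18 genes were higher and none lower, the same numbers as when adjusted over the list alone (camera adjusted p = 0.0154, 0.7 with an estimated correlation). Cyp8b1 and Abcb4 were 13.8-fold and 4.13-fold lower with MeUAB30, Abcg5, dim with MeUAB30, was lower too (adjusted p = 0.000697), and Nr0b2 was 2.97-fold higher. Of 22 bile acid genes 1 was higher and 4 lower, as when adjusted over the list alone (camera adjusted p = 0.0118, 0.81 with an estimated correlation and 0.0739 without the 4 arrays that stood apart). Acmsd (6.43-fold), Gnmt (2.91-fold), Thrsp (1.98-fold) and Acaca, acetyl-CoA carboxylase (2.16-fold), were higher with MeUAB30. Of 20 fatty acid synthesis genes 3 were higher and 2, Fads1 and Fads2, lower, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0242, 0.908 with an estimated correlation, 0.0838 with the intensity range as a covariate and up to 0.0897 without MeUAB30 2, 3 or 4). Nr1d1, the clock repressor REV-ERB alpha, was 5.71-fold higher with MeUAB30, the P450 Cyp2c13 4.76-fold higher, Rab30 4.57-fold lower, and Plppr1, dim with MeUAB30, lower (adjusted p = 0.000106).

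For other genes no difference between the analogs was shown. The log2 difference was 0.28 for Cyp7a1 (95% interval -0.53 to 1.10), 0.18 for Ehhadh (-0.06 to 0.42), -0.26 for Pdk4 (-0.57 to 0.05), 0.02 for Rarb (-0.28 to 0.32) and 0.05 for Rxra, the gene of RXR alpha (-0.17 to 0.27). Scd differed by 0.57 (0.27 to 0.87) with an adjusted p of 0.0579, and it passed in 11 of the alternatives tried. Decr2 and Crot were higher with MeUAB30 (adjusted p = 0.00213 and 0.0253), the 2 peroxisomal genes of 20 that passed, against 5 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0159, 0.961 with an estimated correlation and 0.0557 with the intensity range as a covariate). The higher share of 50.6% was 63.3% of 1341 with array weights, 64.2% of 165 without UAB30 1, 65.8% of 155 without MeUAB30 1 and 39.7% of 126 without MeUAB30 4. The count of 172 was 114 with each array centred on its median, 339 without the 4 arrays that stood apart, and 86, 96 and 88 without UAB30 2, 3 or 4 and 94 and 89 without MeUAB30 2 or 3.

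Targretin, at 150 ppm, differed from UAB30 in 150 genes, 75 higher and 75 lower. Fatty acid synthesis again stood out, with 15 of 20 genes higher and none lower, 17 when adjusted over the list alone (median 0.87, camera adjusted p = 1.01e-48), the other list call that held with an estimated correlation (adjusted p = 0.00532). Pnpla3 was 20.6-fold, Elovl6 4.95-fold and Me1 3.04-fold higher, Acaa1b 3.56-fold and Ehhadh 2.32-fold. Cyp7a1 was 5.11-fold higher with Targretin (log2 difference 2.35, 95% interval 1.54 to 3.17), and Cyp8b1 14.5-fold lower. Cyp1a1 was 28.5-fold lower with Targretin (adjusted p = 1.29e-06). Its Targretin arrays spread from 5.63 to 7.98, around and above the filter threshold, so that fold is uncertain. Slc28a2 and Akr1b7 were 3.39-fold and 2.74-fold lower. Cyp26a1 differed by 0.35 (95% interval -0.16 to 0.87), which did not pass. The count was 96, 99, 96 and 98 without UAB30 1, UAB30 3, UAB30 4 or Targretin 4, and 228 without Targretin 2 and Control 3. The higher share of 50% was 67.1% without those 2 arrays, 65.4% without the 4 arrays that stood apart and 26.8% of 624 genes with the intensity range as a covariate, all chosen after seeing the data. It was 61.6% of 151 without Targretin 2 and 61.5% of 96 in a fit of the 8 arrays alone.

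Between Targretin (150 ppm) and MeUAB30 (200 ppm) 678 genes differed, 206 higher and 472 lower with Targretin. Metallothionein Mt2A was 16.3-fold and Mt1 6.84-fold lower with Targretin, Cyp26a1 9.33-fold lower, Cyp26b1, dim with Targretin, lower (adjusted p = 4.51e-06), and Akr1b10 and Gnmt 6.34-fold and 5.7-fold lower. Higher with Targretin were Pnpla3 (13.5-fold), Cyp17a1, a steroid hydroxylase (7.29-fold), Rnf125 (4.6-fold), Acot1 (4.31-fold), Cyp7a1 (4.2-fold), Nr1i3 (3.63-fold) and Ppara, the gene of the peroxisome proliferator-activated receptor alpha (2.33-fold). Of 20 fatty acid synthesis genes 11 were higher and none lower with Targretin, 13 and 1 when adjusted over the list alone (camera adjusted p = 1.69e-18, 0.153 with an estimated correlation). Of 22 bile acid genes 7 were higher and none lower, Abcb4 by 3.59-fold and the efflux transporter Abcc3 by 3.03-fold, with 8 and 2 when adjusted over the list alone (camera adjusted p = 1.52e-06, 0.65 with an estimated correlation). Nr0b2 and Abcg5, the latter dim with MeUAB30, differed by -0.14 (-0.51 to 0.23) and 0.70 (-0.04 to 1.43), log2 differences with 95% intervals, and did not pass. The share of higher genes, 30.4%, was 54.9% of 1272 genes without the 4 arrays that stood apart, 63.0% of 1224 without Targretin 2 and Control 3 and 47.3% of 2127 with array weights, the first pair chosen after seeing the data. It was 56.2% of 665 without Targretin 2 and 44.8% without MeUAB30 4. The count was 358, 369 and 440 without MeUAB30 2, 3 or 4.

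The responses to the diets overlapped in part. MeUAB30 and Targretin shared 93 higher genes, against 14.5 for independent lists of those sizes, and 24 lower genes, against 1.66, while 11 genes passed in opposite directions. UAB30 and MeUAB30 shared 5 higher genes and UAB30 and Targretin 3 higher and 1 lower. All diets were compared with the same 4 Control arrays, which alone make changes correlate: 100 simulated pairs of unchanged groups gave a mean correlation of 0.442 and up to 0.947 across genes, and a mean of 3.75 shared calls and up to 369. Across genes, which are not independent replicates, the log2 changes correlated at 0.651 for UAB30 and MeUAB30, 0.519 for UAB30 and Targretin and 0.493 for MeUAB30 and Targretin. With the Control arrays split so that each diet had its own 2, the correlations were 0.259 to 0.362, 0.0658 to 0.254 and 0.138 to 0.362. Covariances were 0.0520, 0.0320 and 0.0484 against a simulated mean of 0.0157, a difference of 0.0363, 0.0162 and 0.0327, but a simulated pair reached 0.0688, above all 3. With split controls they were 0.0271 to 0.0371, 0.00586 to 0.0183 and 0.0173 to 0.0398. With split controls 2 to 8 genes were called for UAB30, 102 to 1742 for MeUAB30 and 27 to 51 for Targretin. MeUAB30 and Targretin then shared 14 to 20 calls, against 0.299 to 2.30 for independent lists of those sizes, UAB30 and MeUAB30 0 to 2, against 0.0474 to 0.233, and UAB30 and Targretin 0. Leaving out Control 2 raised the UAB30 overlaps to 31 and 17, and the 117 shared calls of MeUAB30 and Targretin were 206 without Targretin 2, 69 without Control 1, 71 without Targretin 4, 73 without Control 4 and 77 without MeUAB30 3.

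**Figure D4:**
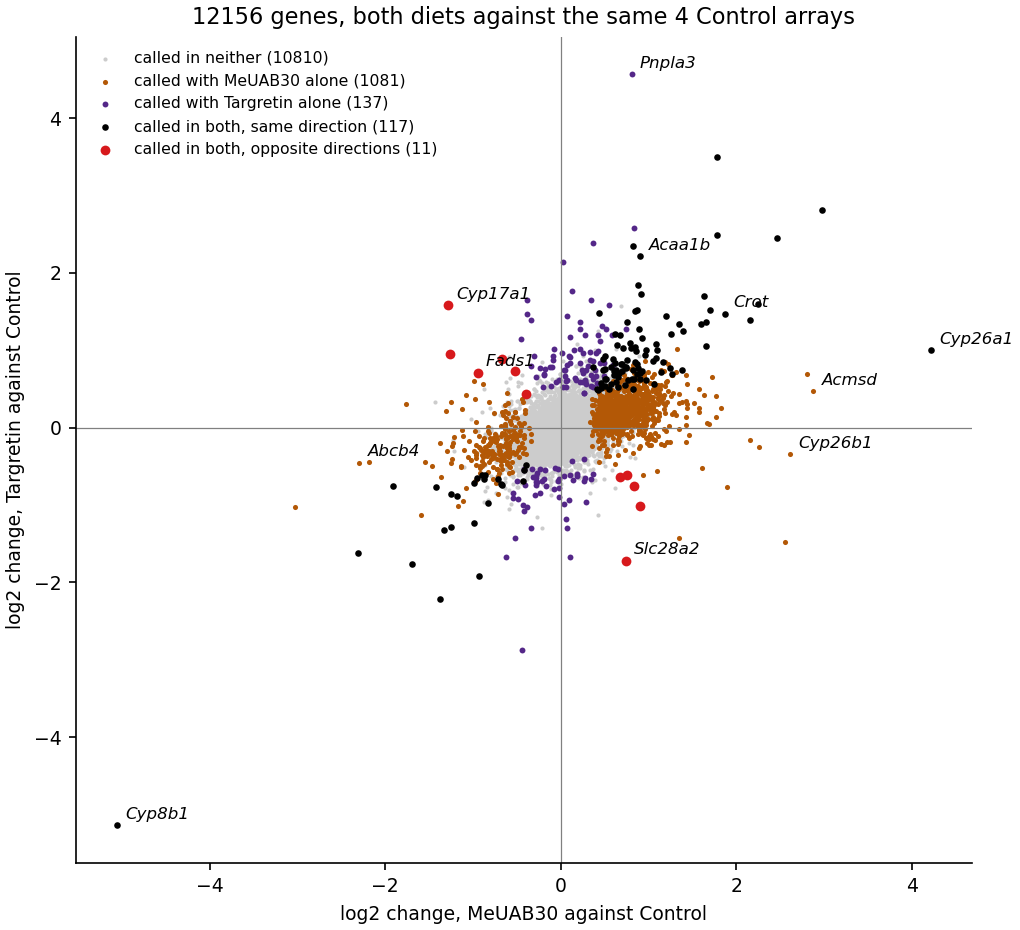
Log2 change of each of 12156 genes with MeUAB30 (x axis) and with Targretin (y axis), both against the same 4 Control arrays; black points passed in both comparisons in 1 direction and red points in opposite directions. The 117 shared calls lie in the upper right and lower left, and 11 genes, Cyp17a1, Fads1 and Slc28a2 among them, lie in the other corners.

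The 11 genes with opposite changes included both desaturases of polyunsaturated fatty acids. Fads1 and Fads2 were 3.15-fold higher and 1.55 higher on the log2 scale with Targretin than with MeUAB30 (adjusted p = 2.49e-07 and 2.84e-07). Cyp17a1, Rnf125, Slco2a1 and Ugt1a1 likewise rose with Targretin and fell with MeUAB30, and Slc28a2, Lrat, Akr1b8, Oaf and Ugt2a3 did the opposite. Ugt1a1 was read by 1 probe set of a family with shared exons.

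A score over the 116 genes that passed between Targretin and Control in a fit of those 8 arrays, 89 of them higher with Targretin, placed the other agonists on the Targretin response. The mean score above Control was 1.33 ± 0.0193 for Targretin, 0.626 ± 0.136 for MeUAB30 and 0.342 ± 0.0749 for UAB30 (log2, mean ± SD, n = 4), with Control at 0 ± 0.107. MeUAB30 exceeded UAB30 by 0.285, and all 4 MeUAB30 arrays lay above all 4 UAB30 arrays, narrowly, with 0.429 on MeUAB30 1 and 0.414 on UAB30 1 (two-sided exact permutation test, 70 permutations, p = 0.0286, the smallest they can give). The genes were chosen with the Control arrays that also set the zero. They were also chosen with the Targretin arrays, so the Targretin mean and its small SD come in part from that choice. On genes chosen without it, Targretin 2 scored 0.973, against a mean of 1.19 for the other Targretin arrays. With Control arrays split between choice and baseline the scores rested on other and fewer genes, 27 to 51, and were 0.400 to 0.561 for UAB30 and 0.879 to 1.02 for MeUAB30. The p rose to 0.0571 without any 1 of the UAB30 arrays and to 0.0857 without Targretin 2, where the difference was 0.186. In each group the array with the narrowest intensity range scored lowest, with 0.256 on UAB30 3, 0.429 on MeUAB30 1, 1.31 on Targretin 2 and -0.153 on Control 3. The score was not adjusted for that range.

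**Figure D5:**
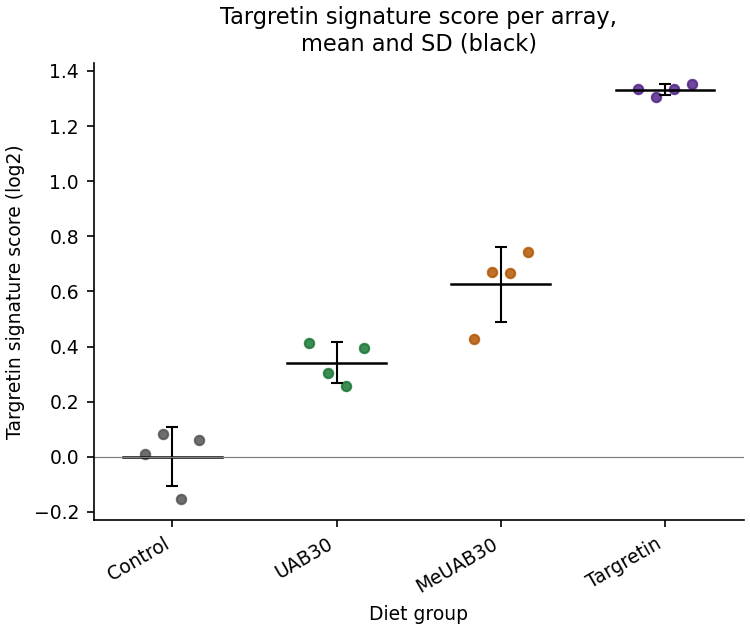
Targretin signature score of each array (y axis, mean log2 change over 116 genes in the Targretin direction, above the Control mean), 4 points per diet with group mean and SD in black. Targretin averaged 1.33, MeUAB30 0.626 and UAB30 0.342.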

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

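The tests of the intensity range, of both array labels, of the AhR-type genes and of the MeUAB30 counts were chosen only after the result was seen, the bounds for both labels were rewritten after their values were known, and the Nrf2 test was widened to genes shared with the AhR after its value was known; the test of other cell types and the splits of the samples were set beforehand.

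In 36 of 448 groups of 4 arrays, 8.04% against about 5% by chance, 1 array lay far from its mates, with a gap to the nearest array, as a share of the range of the group, above the 95% critical value of Dixon. Targretin 2 was that array in 9 of them and Control 3 in 7. The gaps of Targretin 2 were 0.858 of the range for Abca1, 0.911 for Angptl4, 0.934 for Ccng1, 0.942 for Crot, 0.895 for Cyp2c22, 0.849 for Cyp51, 0.830 for Psmb8, 0.913 for Spink1 and 0.848 for the intensity range, each on the low side. Control 3 was low by 0.910 for Acot2, 0.891 for Car12, 0.878 for Pdk4, 0.8292 for Plppr1, 0.841 for Rarb, 0.888 for Rnf125 and 0.894 for the mean correlation with its mates.

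Other arrays lay apart in single genes. The gap was 0.946 for A1bg, 0.907 for Ddc, 0.847 for Hyal1 and 0.904 for Nr1i3 on MeUAB30 4. On MeUAB30 1 it was 0.936 for Acot1, 0.831 for Elovl6, 0.895 for Inhbe and 0.880 for Rarb, and on MeUAB30 2 0.873 for Akr1b10, 0.949 for Akr1b7 and 0.925 for Bhlhe40. Zbtb16 stood at 0.921 on MeUAB30 3, Bhlhe40 at 0.854 on UAB30 3, and Abcg1 and Cyp1a1 at 0.840 and 0.872 on UAB30 1. Control 2 was high by 0.866 for Cyp1a2, 0.842 for Cyp3a23-3a1 and 0.840 for Psmb8, Targretin 1 by 0.904 for Scd and Targretin 4 by 0.844 for Elovl6.

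The 4 arrays that stood apart may share an intensity range compressed relative to their group. Within groups, the score on the first principal component and the intensity range deviated together over the 16 arrays (Pearson r = -0.967, permutation p = 1e-05, the smallest that 100000 permutations can give; Spearman rho = -0.944, permutation p = 5e-05, the smallest of 20000), and r was -0.937 without Targretin 2 and Control 3. Both measures were computed from the same intensities, so their relation describes these arrays and is not independent support. RNA of another cell type was left open, because its test looked only for a gain in non-hepatocyte markers. The highest median of such a list in Targretin 2 or Control 3 was 0.307 above the group mates. With genes binned by mean level, median deviations fell to -0.473 in Targretin 2 and -0.325 in Control 3, which could hide a gain. The dimmest bin lay at -0.0292 and 0.115. Kupffer markers lay at -0.948 and -0.590, and sinusoidal endothelial markers at -0.679 and -0.474. A loss of RNA of these cells was not tested. A wrong label was argued against for Targretin 2, whose score on genes chosen without it, 0.973, exceeded the highest array of another group, at 0.693, by 0.280 against a largest SD of 0.135, though the mean of its mates was 1.19. Control 3 scored -0.0709 above its mates while the lowest UAB30 array scored 0.281. What compressed the range stays open, and no biological explanation was tested.

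For genes that passed in opposite directions in a pair of diets the direct difference was also read. With MeUAB30 against UAB30 the log2 difference was -1.87 for Cyp1a2 and -1.63 for Ugt1a6. With Targretin against MeUAB30 it was 2.87 for Cyp17a1, 2.20 for Rnf125, 1.66 for Fads1, 1.55 for Fads2, 1.26 for Ugt1a1 and 0.82 for Slco2a1. It was -2.47 for Slc28a2, -1.92 for Ugt2a3, -1.58 for Lrat, -1.37 for Oaf and -1.31 for Akr1b8. All 13 differences passed. Each adds 2 opposite changes that had already passed in the same fit, so the choice of genes all but fixed this outcome.

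Probe sets with no gene name here, which the gene comparisons did not use, also changed. Of 116880 tested by the same model, 6 passed with UAB30, 434 with MeUAB30 and 162 with Targretin against Control, where 6720, 12317 and 7546 had an unadjusted p under 0.05.

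The AhR-type increase with UAB30 was set against 3 technical or narrower explanations. A single array was argued against, since the lowest UAB30 array exceeded the highest of the other 12 arrays by 3.45 on the log2 scale for Cyp1a1. Cyp1a2 transcript read by Cyp1a1 probe sets was argued against by a Cyp1a1 change that exceeded that of Cyp1a2 by 4.75. An Nrf2 response alone was left open by its test. The genes that are not shared were first read by driver. The 4 driven by the AhR and not Nrf2 had a median of 1.26, with Cyp1a1 and Cyp1a2 passing. The 12 driven by Nrf2 and not AhR had 0.155 with 0 passing. The test of the 16 members driven by Nrf2, those shared with the AhR included, gave no verdict (median 0.174, SE 0.116). Nqo1 and Ugt1a6 passed among them, and both are shared. A response of the AhR to this diet may be a further hypothesis, and an AhR ligand other than UAB30 in that 1 diet batch was not tested.

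The larger count with MeUAB30 than with UAB30 was not explained by uneven arrays, since the ratio of the counts was 79.1 without the 4 arrays that stood apart. The share of higher genes with MeUAB30 may in part come from those arrays, as it was 61.3% without them against 79.7% with them. Quantile normalization left it at 76.4%. The intensities were already close in distribution, with 75th percentiles of 65.5 to 67.8, so this could not decide on normalization between arrays. With the intensity range as a covariate, chosen after seeing the data, the share was 47.2%. A difference in exposure between the diets was not tested.

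Chance as the source of the counts was examined by the 35 splits of the 8 arrays of each comparison into 4 and 4. For 5 comparisons 1 split, the real one, gave as many genes, the smallest share that 35 splits can give. That share was not adjusted over the 6 comparisons, so it argues against chance for each alone but does not exclude it. The real counts were 10 genes for UAB30 and 1209 for MeUAB30, 172 for MeUAB30 against UAB30 and 150 for Targretin against UAB30. Each had 0 in the highest other split. For Targretin against MeUAB30 the count was 678, with 4 in the highest other split. For Targretin against Control 2 of 35 splits gave as many genes, so the splits did not argue against chance there. The real count was 265. The other split gave 633 genes, with Targretin 1, 3 and 4 and Control 2 against Targretin 2 and Control 1, 3 and 4. That split puts the arrays with the lowest weights, Targretin 2 and Control 3, on 1 side, and points to a structure of the samples. The real comparison gave 344 genes without those 2 arrays and 1275 with the intensity range as a covariate.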

How the results depend on the processing

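The fits without Targretin 2 and Control 3, without the 4 arrays that stood apart, and with the intensity range as a covariate were chosen after seeing the data. No called result of a named gene or list passed the threshold in the opposite direction under any alternative. Results that were not called are not covered by this statement. Of the results of named genes under alternatives 6110 kept their side of the threshold, 70 passed it and 161 lost it. For lists the numbers were 3122, 43 and 195. These totals include results never called: 187 of 277 named-gene results were called. Under every alternative 3 of 9 calls held for UAB30, 43 of 50 for MeUAB30 and 29 of 37 for Targretin against Control. Between compounds 19 of 20 held for MeUAB30 against UAB30, 19 of 30 for Targretin against UAB30 and 40 of 41 for Targretin against MeUAB30. An estimated correlation ended 57 list calls. The cause of the changes below was not tested, except where fewer arrays set the smallest p. Signal over background could not be examined from the processed intensities, and the filter on dim probe sets stood in for it.

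Called genes are given in the order UAB30, MeUAB30 and Targretin against Control, MeUAB30 against UAB30, Targretin against UAB30 and Targretin against MeUAB30, with 10, 1209, 265, 172, 150 and 678 in the text. Array weights gave 44, 2775, 759, 1341, 457 and 2127, and the covariate 106, 3013, 1275, 717, 624 and 2251. Without the 4 arrays the counts were 31, 2452, 497, 339, 179 and 1272, and without Targretin 2 and Control 3 they were 40, 2349, 344, 426, 228 and 1224. Centring gave 114 for MeUAB30 against UAB30, the median summary 5 for UAB30, and the fit of 8 arrays 116 for Targretin and 96 for Targretin against UAB30. Leaving out 1 array gave 4 to 36, 638 to 1348, 169 to 399, 86 to 165, 96 to 151 and 358 to 665.

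Called lists, 10, 8, 10, 11, 11 and 9 in that order, were 0, 0, 1, 0, 1 and 0 with an estimated correlation. With fry they were 1 for UAB30, 6 for Targretin, 2 for MeUAB30 against UAB30, 4 for Targretin against UAB30 and 5 for Targretin against MeUAB30. The covariate gave 5 for MeUAB30 and 7 for MeUAB30 against UAB30, and the fit without the 4 arrays 4 and 7. Leaving out 1 array gave 6 to 11, 6 to 9, 7 to 13, 9 to 10, 9 to 14 and 7 to 10.

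The correlation of UAB30 with MeUAB30 was 0.709 without Targretin 2 and Control 3, and without the 4 arrays that of UAB30 with Targretin was 0.573 and of MeUAB30 with Targretin 0.529. Leaving out 1 array gave 0.551 to 0.709, 0.481 to 0.617 and 0.468 to 0.569 for UAB30 with MeUAB30, UAB30 with Targretin and MeUAB30 with Targretin. Overlaps in that order were 32, 13 and 177 without Targretin 2 and Control 3, and 25, 15 and 263 without the 4 arrays; quantile normalization gave 9 for the first. Leaving out 1 array gave 2 to 31, 1 to 17 and 69 to 206.

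The difference of the Targretin score between MeUAB30 and UAB30 was 0.287 with the mean summary (exact permutation p = 0.0571), 0.187 without Targretin 2 and Control 3 (exact permutation p = 0.0571) and 0.199 without the 4 arrays (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). Leaving out 1 array gave 0.186 to 0.408, with exact permutation p from 0.0286 to 0.0857.

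The replicate numbers did not pair the arrays as a whole: of 24 pairs with the same number 10 had a correlation of deviations over 0.1, with a median of -0.00322 against 0.0594 for other pairs, and 5 of 16 arrays correlated best with an array of their own number. The arrays numbered 4 did deviate together in every pair, from 0.177 for MeUAB30 4 and Control 4 to 0.318 for UAB30 4 and MeUAB30 4. Unlike numbers reached 0.674, for Targretin 2 and Control 3. With the replicate number as a block the counts were 11, 1008, 212, 138, 119 and 521, and the score difference was 0.285 (exact permutation p = 0.125, the smallest possible within numbers). The list calls that the block ended were those of the stress response with UAB30 and of the urea cycle with Targretin.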

Other observations

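Mt2A, a metal-binding metallothionein, rose 5.87-fold with MeUAB30 (log2 change 2.55, SE 0.42, adjusted p = 0.000994, n = 4 arrays per group, limma), and with Targretin it was lower than with UAB30 by 4.38-fold (adjusted p = 0.0123). That last call was lost without UAB30 1 or Targretin 4, up to 0.0597. Of 17 circadian clock genes 4 rose and 1 fell with MeUAB30, 6 and 4 when adjusted over the list alone (camera adjusted p = 0.969): Dbp, a clock-controlled transcription factor, rose 3.17-fold (log2 change 1.04 without MeUAB30 3 against 1.66 with it) and Bhlhe40 2.6-fold. The acute phase genes Orm1 and Lcn2 rose 3.55-fold and 1.74-fold with MeUAB30, among 5 of 23 that rose with none falling, also when adjusted over the list alone (camera adjusted p = 0.0666). With UAB30 none of the 23 passed and 2 rose when adjusted over the list alone, with 20 positive, and the list passed (median 0.14, camera adjusted p = 0.0153, 0.8295 with an estimated correlation, 0.0847 without UAB30 1). With Targretin 4 of 23 were lower than with MeUAB30, 7 when adjusted over the list alone (camera adjusted p = 0.00597, 0.74 with an estimated correlation, 0.0735 without MeUAB30 1 and 0.0758 without the 4 arrays that stood apart). Against UAB30 none differed, also when adjusted over the list alone, while the list passed (median -0.16, camera adjusted p = 0.00179, 0.7 with an estimated correlation).

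Of 20 interferon response genes 5 rose with MeUAB30 and none fell, also when adjusted over the list alone, with Ifi27 at 2.71-fold and the immunoproteasome subunit Psmb8 at 2.14-fold (median 0.37, camera adjusted p = 0.00354, 0.908 with an estimated correlation, 0.372 without the 4 arrays that stood apart, 0.0852 without Control 3, 0.0696 with the intensity range as a covariate). Kupffer cell and macrophage markers had a median of 0.47 in the same comparison (camera adjusted p = 0.128, 0 of 14 passing, 4 when adjusted over the list alone). Growth hormone and sex-biased genes had 1 member that rose and 4 that fell of 22 with Targretin, 1 and 6 when adjusted over the list alone, Akr1b7 and A1bg among the fallen (median -0.15, camera adjusted p = 0.0216, 0.7 with an estimated correlation, 0.07 without the 4 arrays, 0.13 without Control 3, 0.205 with the intensity range as a covariate). Gluconeogenesis genes had 3 of 20 that rose with Targretin and none that fell, 6 and 1 when adjusted over the list alone, with Igfbp1, an insulin-regulated binding protein, at 3.15-fold and the glycogen phosphorylase Pygl at 1.61-fold (camera adjusted p = 0.00166, 0.7 with an estimated correlation). With MeUAB30 the stress response genes Herpud1 and Asns rose 1.73-fold and 1.86-fold, and the p53 targets Ccng1 and Gadd45a 1.94-fold and 1.92-fold, while the stress and p53 lists as wholes did not pass (camera adjusted p = 0.868 and 0.741). With UAB30 the stress list passed in the downward direction (median -0.0049, with 10 of 21 positive, against a median of 0.05 over all genes; camera adjusted p = 0.0279, 0.908 with an estimated correlation), with none passing and 1 lower when adjusted over the list alone. That call was lost without UAB30 2 or 4 or Control 2 or 3 (adjusted p up to 0.226). None of the 28 cell cycle genes passed with any diet against Control in limma, and the camera adjusted p was 0.0256, 0.867 and 0.668 for UAB30, MeUAB30 and Targretin (0.7 for UAB30 with an estimated correlation, 0.07 without the 4 arrays and up to 0.159 without UAB30 2 or 3 or Control 2).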
